A study of Homo sapiens with 12 samples.

How the data were processed

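RNA sequencing measured gene expression in LS180, an established human colorectal cancer cell line that makes intestinal mucus proteins. Derivatives of the line carry a doxycycline-inducible construct for GFP, for wild-type SOX9 or for M303, which the series design describes as a shortened form of SOX9. Each line was analysed without doxycycline and after 24 h in 0.5 µg/ml doxycycline, which gives 6 groups of 2 libraries and 12 libraries in all. Per the labels' protocols, mRNA was captured with oligo(dT) beads and sequenced as 150-bp read pairs.

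The deposited unit is the raw read count per gene. Per the submitters' processing notes, reads were aligned to hg38 with STAR 2.7.0a, and the deposited count table was made with featureCounts. Per the file headers, the counter was featureCounts version 2.0.1 with the annotation of Ensembl release 101. The recorded command has no paired-end option, so each mate was counted as a read, and the totals are of mates, not of fragments. It also has no strand option and does not count reads that map to several places. The Poisson part of the counting error is therefore larger than the totals would imply, and close gene families such as DEFA5 with DEFA6, or CEACAM1 with CEACAM5, may lose reads they share. Without strand, reads from a gene and an overlapping gene on the opposite strand cannot be separated. This applies to SOX9, which overlaps SOX9-AS1 and 1 further gene there, and to LYZ, which overlaps 1. The SOX9 count pools endogenous transcripts with construct transcripts, as far as these carry SOX9 sequence covered by the annotation.

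The table has 60671 genes, of which 42020 (69.3%) have a symbol in the gene name table used here. No column was left unused and 0 entries named no gene. Totals ranged from 31012775 to 48529770 counts per library. No pair of libraries of a group matched within counting noise, so none was treated as 1 library counted again, which does not show that they are independent. Nothing states that the duplicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

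Counts were tested with edgeR 4.0.16 in R 4.3.3, using the robust quasi-likelihood F-test. All 12 libraries entered 1 model with 1 mean per group, and the groups shared 1 estimate of the spread with 6 residual degrees of freedom. Library sizes were scaled with TMM factors, which ranged from 0.981 to 1.02. The filter filterByExpr left 18219 genes. The biological coefficient of variation was 10.6%. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, and every adjusted p of a gene below is from this test. CPM values are counts scaled by library size, computed from the deposited counts with the TMM factors. The median standard error of a log2 fold change, among genes with a mean above 1 CPM, was 0.12 for each induction. It was 0.17 for a difference between 2 inductions.

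There were 8 comparisons. These are induction of SOX9, of M303 and of GFP (with against without doxycycline in the same line), the 3 differences between these inductions, and the uninduced SOX9 and M303 lines against the uninduced GFP line. Differences between inductions were tested as interaction terms. Each construct was in its own line, so these differences cannot separate a construct from the line that carries it.

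The comparisons, alternatives, gene lists and the rule for named genes were set before the data were examined. The rule names SOX9 and 15 genes fixed in advance. It adds, among called genes with a mean of at least 1 log2 CPM, a symbol and, in contrasts of 2 groups, no overlap of the groups, the 8 highest and 8 lowest fold changes for SOX9 and for M303 induction. For SOX9 against M303 induction it adds 6 and 6, and elsewhere 3 and 3. Of each list it adds the 3 called members with the smallest adjusted p. A gene that the rule selects is not reported here. The 25 lists cover intestinal stem cell, WNT target, enterocyte differentiation, goblet cell, Paneth cell, enteroendocrine cell, tuft cell, fetal or regenerative epithelium, YAP target, cartilage, hepatobiliary and pancreatic duct, Notch pathway, G1/S cell cycle, G2/M cell cycle, p53 target, integrated stress response, mitochondrially encoded, interferon response, inflammatory NF-kB, hypoxia and glycolysis, cholesterol synthesis, mesenchymal and TGF-beta, fibroblast, blood and immune cell, and endothelial cell genes. Of the listed symbols, 2 had no match in the table by name (SOD2, and DDX58, an older name). Lists were tested with camera from limma 3.58.1 at a preset correlation of 0.01, and again with an estimated correlation and with fry, where at least 5 members were tested. List p-values were adjusted over the lists of a comparison. The filter left 6 of 11 Paneth cell, 24 of 38 enterocyte, 8 of 22 cartilage, 7 of 20 enteroendocrine and 7 of 11 tuft genes to test. In the uninduced libraries 4 Paneth cell, 1 enteroendocrine and 3 tuft genes had a mean of at least 1 CPM.

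Alternatives were other size factors or none, DESeq2 1.42.0, no or a stricter filter, only the libraries of a contrast, a block for the replicate number, a fold threshold and leaving out each library in turn. A covariate for the share of ribosomal protein genes was chosen after seeing the data. On simulated counts drawn from the means of these libraries, the test called 76.1%, 97.0% and 100% of genes changed by 1.5-fold, 2-fold and 4-fold for SOX9 induction, over 17547 genes. For M303 induction the shares were 68.7%, 91.0% and 98.5% over 17545 genes. For the difference of both they were 29.9%, 79.1% and 98.5% over 17589 genes. False calls made up 6.19%, 11.3% and 8.61% of the calls. The gene numbers given are of all genes tested. The changed genes, 67 or 66 per fold size, were drawn among genes with a mean of at least 2 CPM. Each comparison had its own draw in a single run. The shares therefore do not cover weaker genes, and small differences between comparisons may come from the draw. All changed genes were planted together, which eases the adjusted threshold. The shares therefore overstate the power where few genes change.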

Results

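The transcriptomes of 12 LS180 libraries were counted per gene. LS180 is a human colorectal cancer line with goblet-like features. Its 3 derivatives express GFP, wild-type SOX9 or the shortened SOX9 form M303 when doxycycline is added. SOX9 is a transcription factor of intestinal stem and progenitor cells and of Paneth cells. The series title concerns a stem-cell-like program driven by SOX9 and a block of intestinal differentiation. The uninduced groups had 31012775 and 36134127 counts (GFP), 33448241 and 37426903 (M303), and 37218004 and 36168243 (SOX9). The induced groups had 38009645 and 36108277 counts (GFP), 41893421 and 35029487 (M303), and 48529770 and 31317894 (SOX9). The most abundant gene, EEF1A1, took 1.23% to 1.37% of the counts of a library.

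The SOX9 gene (ENSG00000125398, GRCh38 chromosome 17, 72121020 to 72126416, plus strand) was measured first, as a check of the labels. Without doxycycline it stood at 396 ± 4.63 CPM in the GFP line, 383 ± 22.7 CPM in the M303 line and 369 ± 16.8 CPM in the SOX9 line (SD, n = 2 each). With doxycycline it rose to 736 ± 34.7 CPM in the SOX9 line, a log2 fold change of 1.00 (SE 0.07, edgeR adjusted p = 4.11e-08). In the M303 line it rose to 843 ± 34.4 CPM, a log2 fold change of 1.14 (SE 0.07, adjusted p = 2.84e-08). In the GFP line it was 388 ± 24.0 CPM with doxycycline, a log2 fold change of -0.03 (adjusted p = 1.00). The rise with SOX9 and the rise with M303 differed by -0.14 on the log2 scale (95% CI -0.36 to 0.07, adjusted p = 0.891). The count pools endogenous and construct transcripts, so the share of each is unknown, and protein was not analysed here.

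**Figure D1:**
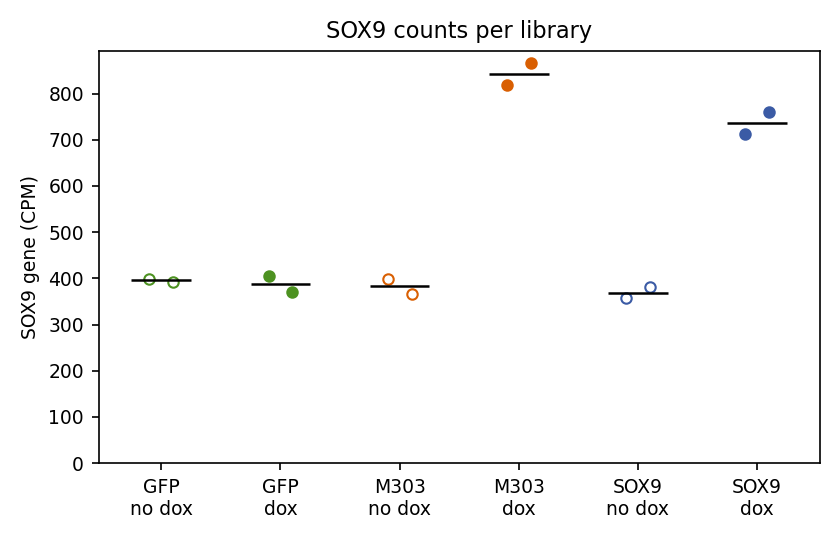
SOX9 expression in CPM (vertical axis, linear from 0) in the 6 groups of LS180 libraries (horizontal axis); each circle is 1 library, open without and filled with doxycycline, and the black bar is the mean of 2. The induced M303 libraries stand at 818 and 867 CPM and the induced SOX9 libraries at 712 and 761 CPM, above the other 8 libraries, which lie between 357 and 405 CPM.

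Inducing wild-type SOX9 raised 4 of the 6 Paneth cell genes tested (of 11 listed) and lowered 15 of 23 goblet cell genes tested. Of 16 stem cell genes tested 7 rose and 1 fell. Of 24 enterocyte genes tested (of 38 listed) 7 fell and 3 rose. LYZ, the antimicrobial enzyme lysozyme of Paneth cells, rose from 51.8 ± 6.90 to 584 ± 7.99 CPM (SD, n = 2). MUC2, the main secreted mucin of goblet cells, fell from 66.0 ± 4.65 to 22.7 ± 2.90 CPM. KRT20, a keratin of differentiated colonocytes, fell from 9.18 ± 0.95 to 3.05 ± 0.39 CPM. The comparison asks which genes respond to 24 h of wild-type SOX9. Of 18219 genes tested, 541 were called by edgeR, 330 higher and 211 lower, and 80 and 38 of these changed by at least 2-fold. DESeq2 called 772, of which 536 were shared. Leaving out 1 library moved the count to 301 (SOX9 without doxycycline, replicate 2), 270 (SOX9 with doxycycline, replicate 1) or 231 (SOX9 with doxycycline, replicate 2). Without replicate 1 of uninduced SOX9 the split of 527 calls turned to 252 higher and 275 lower.

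The 8 highest fold changes under the naming rule included 3 genes of Paneth cell secretion. DEFA5, an alpha-defensin, had a log2 fold change of 5.75 (SE 0.54, adjusted p = 1.59e-04), from a low level of 0.65 ± 0.52 to 35.6 ± 1.92 CPM. DEFA6, another alpha-defensin, rose by 3.80 (SE 0.35, adjusted p = 1.28e-06) and LYZ by 3.50 (SE 0.10, adjusted p = 2.89e-15). TCN1, a vitamin B12 binding protein, rose by 3.73 and PLEKHS1 by 3.50, from low levels of 0.71 and 1.02 CPM. EDAR, the ectodysplasin receptor, rose by 2.60, the interferon-inducible gene IFI6 by 2.33 and CYB5R2 by 2.31. Of the 8 lowest, FABP2, the intestinal fatty acid binding protein, had a log2 fold change of -2.01 (SE 0.25, adjusted p = 3.12e-05), and its relative FABP1 one of -1.51. ZG16, a lectin of goblet cell granules, had -1.79, and MUC2 had -1.54 (SE 0.14, adjusted p = 1.53e-06). KLK3 had -1.87, KRT20 -1.60, NXPE1 -1.56 and NEURL1 -1.55. The call of NXPE1 was lost without any of 3 libraries, with the highest adjusted p, 0.351, without replicate 2 of induced SOX9.

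**Figure D2:**
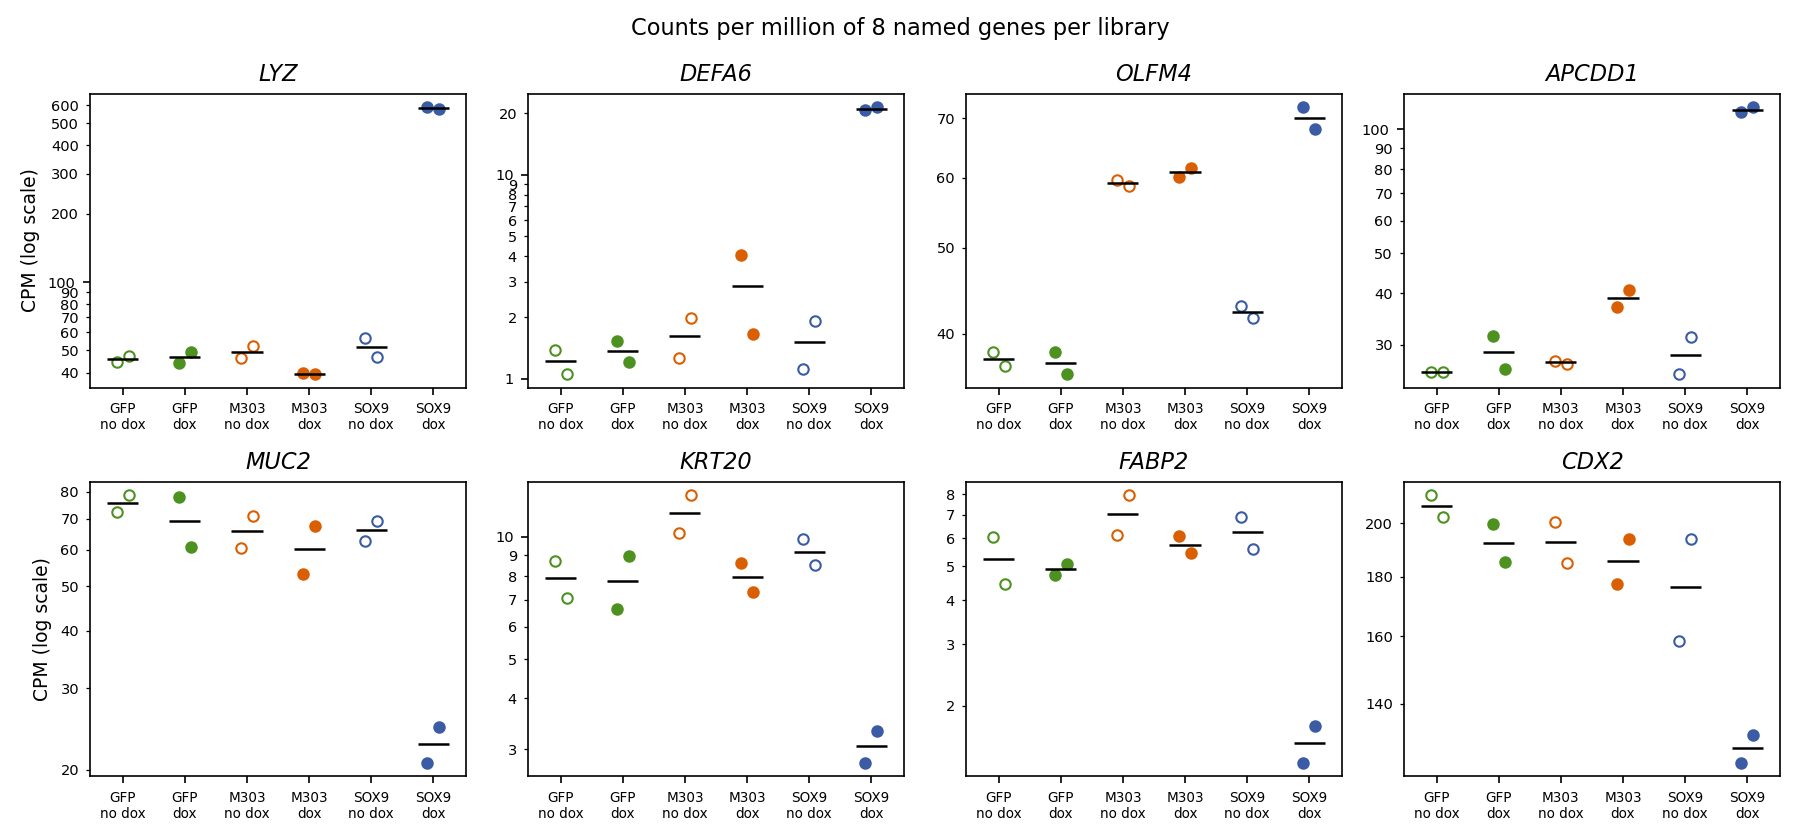
Expression in CPM (vertical axes, log scale, a separate range per gene) of 8 named genes in the 6 groups; each circle is 1 library, open without and filled with doxycycline, and the black bar is the mean of 2. LYZ stands near 584 CPM and MUC2 near 22.7 CPM in the induced SOX9 libraries, against 39.5 and 60.3 CPM in the induced M303 libraries.

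Goblet cell genes fell as a list. Of 23 tested members 15 fell and 0 rose over all genes; adjusted over the list alone, 17 fell and 1 rose. The median log2 fold change was -0.85 (camera adjusted p = 1.14e-47, and 8.86e-05 with an estimated correlation). REG4, a secreted lectin, had -1.04 (adjusted p = 6.08e-08), AGR2, a protein disulfide isomerase needed for mucin folding, -0.85 (adjusted p = 1.01e-07) and the transcription factor CREB3L1 -1.10 (adjusted p = 1.30e-07). ATOH1 and SPDEF, the transcription factors of secretory and goblet cell fate, had -1.25 and -1.21; SPDEF was chosen after values were seen. TFF3, the goblet cell trefoil factor, had -0.80 (adjusted p = 0.034), and its call was lost without any of 8 libraries, with an adjusted p up to 0.291 without replicate 2 of uninduced SOX9.

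Paneth cell genes rose, with 4 of 6 tested members higher and 0 lower over all genes; adjusted over the list alone, 4 were higher and 1 lower. The median was 2.21 (camera adjusted p = 1.23e-39, and 0.0011 with an estimated correlation). The members were LYZ, DEFA5, DEFA6 and PLA2G2A, a secreted phospholipase, which rose by 0.93 (adjusted p = 6.72e-07).

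Intestinal stem cell genes rose as a list. Of 16 tested members 7 rose and 1 fell over all genes, and 9 rose and 1 fell adjusted over the list alone. The median was 0.23 (camera adjusted p = 2.96e-13, and 0.0017 with an estimated correlation). SMOC2, a matricellular protein of crypt base cells, rose by 1.31 (adjusted p = 1.45e-08), OLFM4, a secreted glycoprotein of stem cells, by 0.73 (adjusted p = 1.18e-05) and LRIG1, a receptor regulator, by 0.59 (adjusted p = 1.90e-04). The member that fell was PTPRO, with -0.54, chosen after values were seen. LGR5 and ASCL2, the best known stem cell markers, had log2 fold changes of 0.25 and 0.22 that were not called (adjusted p = 0.173 and 0.228). PROM1 was not tested, because its highest count in any library was 13.

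WNT target genes rose as a list, with 3 of 17 tested members higher and 0 lower over all genes, and 8 and 0 adjusted over the list alone. The median was 0.22 (camera adjusted p = 6.91e-09, and 0.0035 with an estimated correlation). APCDD1 and NKD1, both inhibitors of WNT signalling, rose by 1.98 (adjusted p = 6.15e-10) and 1.14 (adjusted p = 2.15e-07). TNFRSF19, also in the stem cell list, rose by 1.55, but its call was lost without replicate 2 of uninduced or of induced SOX9 (highest adjusted p = 0.0713, without the latter). AXIN2 and MYC, fixed in advance, had -0.05 and -0.17 and were not called.

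Enterocyte genes fell as a list and went both ways singly. Of 24 tested members 7 fell and 3 rose over all genes; adjusted over the list alone, 9 fell and 3 rose. The median was -0.24 (camera adjusted p = 7.23e-06, and 0.0083 with an estimated correlation). LGALS4, a galectin of the gut epithelium, had -0.67 (adjusted p = 1.80e-06). CDX2, the intestinal identity transcription factor, had -0.46 (adjusted p = 0.0042), a call lost without replicate 2 of uninduced SOX9 (adjusted p = 0.111) or replicate 1 of induced SOX9 (adjusted p = 0.0777). The 3 that rose were MUC13, a membrane mucin, by 0.73, CEACAM1, an adhesion molecule, by 0.70 and SLC26A2, a sulfate transporter, by 0.55; the last 2 were chosen after values were seen. CEACAM5 had -0.10 and was not called.

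Shifts were called for 4 further lists. Of 15 mesenchymal and TGF-beta genes 5 rose and 0 fell over all genes, 7 and 0 adjusted over the list alone, with a median of 0.39 (camera adjusted p = 7.23e-06, and 0.040 with an estimated correlation). Of these, ID4 rose by 0.88. Of 17 YAP targets 3 rose and 0 fell by either count, with a median of 0.21 (camera adjusted p = 4.75e-05, and 0.0116 with an estimated correlation). These were the matricellular protein CCN2, by 0.82, the ectonucleotidase NT5E, by 0.65, and IGFBP3, by 0.56. Of 22 cholesterol synthesis genes 7 fell and 1 rose over all genes, 9 and 1 adjusted over the list alone, with a median of -0.17 (camera adjusted p = 3.42e-05, and 0.0109 with an estimated correlation). INSIG1, a sterol sensor partner, had -0.44, while HMGCS1, an enzyme early in the pathway, rose by 1.03 (adjusted p = 9.83e-08). The 13 mitochondrially encoded genes had a median of -0.20 (camera adjusted p = 5.61e-05, but adjusted p = 0.291 with an estimated correlation). None was called over all genes, and 6 were lower adjusted over the list alone. This list also had a camera adjusted p of 0.0524 without replicate 2 of induced SOX9. The call of IGFBP3 was lost without replicate 2 of induced SOX9 (adjusted p = 0.0593). That of STARD4, with -0.53, was lost without the same library (adjusted p = 0.172) or replicate 1 of uninduced SOX9 (adjusted p = 0.118).

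Of the remaining lists none was called for SOX9 induction, and several had single members that were. In the fetal or regenerative list (camera adjusted p = 0.687) 2 of 16 rose and 2 fell over all genes, 3 and 2 adjusted over the list alone. IL33, an alarmin cytokine, had -1.01 and the chaperone CLU -0.79, while the annexin ANXA1 rose by 0.43 and ANXA3, chosen after values were seen, by 0.48. Its median of 0.06 and mean of -0.05 differ in sign, and its test pointed down. Of 18 Notch pathway genes (adjusted p = 0.382) the ligand JAG1 rose by 0.51 and the ligand DLL4 fell by 0.44 on the log2 scale over all genes, with 1 higher and 2 lower adjusted over the list alone. The Notch median was -0.15, the mean 0.02, and the test pointed down. Of 20 interferon genes (adjusted p = 0.735) IFI6 and IFI27 rose and ISG15 and OAS1 fell, by either count; IFI27, with 0.75, was chosen after values were seen. Of 17 NF-kB genes (adjusted p = 0.938) 1 fell by either count, the apoptosis inhibitor BIRC3, with -0.91; the median was -0.02, the mean -0.07, and the test pointed up. Without replicate 1 of induced SOX9 the adjusted p was 0.119 for ANXA1 and 0.0701 for OAS1. Without replicate 2 of induced SOX9 it was 0.200 for DLL4 and 0.0885 for ISG15.

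COL9A3, a cartilage collagen gene, rose by 1.84 (adjusted p = 1.36e-04), the only 1 of 8 cartilage genes higher over all genes; adjusted over the list alone 1 was higher and 1 lower (camera adjusted p = 0.127). Of 12 duct genes (adjusted p = 0.275) the surface glycoprotein CD24 rose by 0.53 and the chloride channel CFTR by 0.28, with 3 higher and 1 lower adjusted over the list alone. Of 22 integrated stress response genes (adjusted p = 0.735) the cystine transporter SLC7A11 rose by 0.56 and TRIB3 had -0.37, with 1 higher and 2 lower adjusted over the list alone. Of 20 p53 targets (adjusted p = 0.785) TP53I3 and SESN1 rose, by 0.62 and 0.46, with 2 higher and 1 lower adjusted over the list alone. Of 20 hypoxia and glycolysis genes (adjusted p = 0.0532) the glycolytic enzymes LDHA and ENO1 had -0.30 and -0.27, with 1 higher and 3 lower adjusted over the list alone. All of these but COL9A3, CD24 and SLC7A11 lost their calls without a single library. The highest adjusted p was 0.207 for TRIB3, 0.256 for SESN1 and 0.390 for TP53I3 without replicate 1 of induced SOX9. It was 0.381 for CFTR and 0.217 for LDHA without replicate 2 of induced SOX9, and 0.317 for ENO1 without replicate 2 of uninduced SOX9.

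No member was called over all genes in the tuft (adjusted p = 0.0532), enteroendocrine (0.244), G1/S (0.244), G2/M (0.735) and fibroblast (0.735) lists. Adjusted over the list alone, 3 tuft genes were higher, 1 enteroendocrine gene was lower, and 0 genes of the other 3 lists were called. The G2/M list had a median of 0.02 and a mean of -0.0026, and its test pointed up. The proliferation marker MKI67 had 0.04 and the cell cycle inhibitor CDKN1A -0.16, neither called. Blood and immune cell genes had 4 members tested and endothelial genes 2, too few for a list test.

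**Figure D3:**
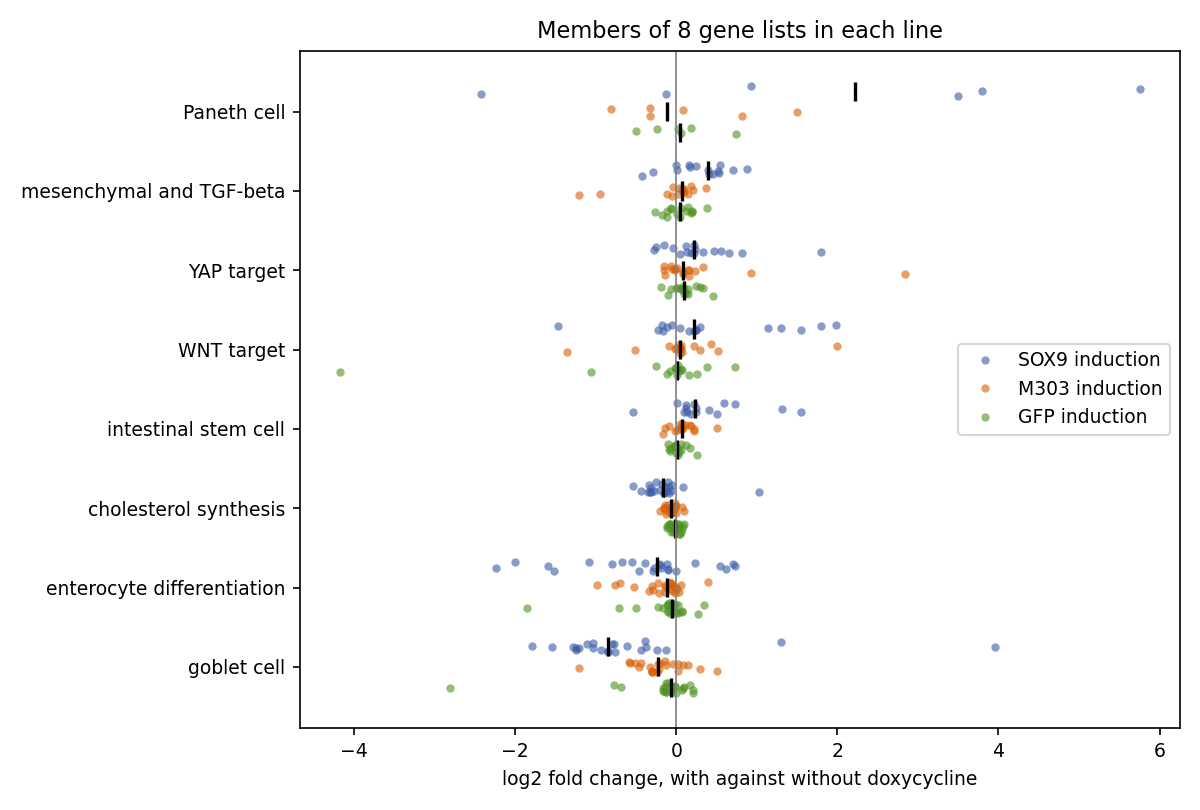
Log2 fold change with against without doxycycline (horizontal axis) of every tested member (dots) of 8 gene lists (vertical axis) in the SOX9, M303 and GFP lines (colours); black bars are list medians. The goblet cell median is -0.85 for SOX9 and -0.22 for M303, and the Paneth cell median is 2.21 for SOX9 and -0.12 for M303.

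On M303 induction 1 gene was called, SOX9 itself, whose count includes construct transcripts, and the goblet cell list was slightly lower. The goblet median was -0.22 against -0.85 with wild-type SOX9. The Paneth cell genes that rose with SOX9 were not called. Mean CPM was higher with than without doxycycline for DEFA5 (2.15 against 0.77), DEFA6 (2.87 against 1.63) and PLA2G2A (120 against 113). LYZ had a log2 fold change of -0.32 (SE 0.09, adjusted p = 1.00). MUC2 had -0.13, KRT20 -0.52, TFF3 -0.52, CDX2 -0.05 and OLFM4 0.04, and none of these was called. The comparison asks what the shortened form does under the same induction. Only 1 gene was called by edgeR, 662 had an unadjusted p under 0.05 and DESeq2 called 3. Without replicate 1 or replicate 2 of induced GFP the edgeR count was 2. Of 23 goblet genes 0 were called over all genes, and 9 were lower and 0 higher adjusted over the list alone (camera adjusted p = 7.69e-11, and 0.0082 with an estimated correlation). Set against GFP induction, the goblet list was not called with an estimated correlation.

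Camera also called 4 more lists for M303, with small medians. Enterocyte genes had -0.11 (adjusted p = 0.0102, but adjusted p = 0.118 with an estimated correlation) and stem cell genes 0.07 (adjusted p = 0.0354, but adjusted p = 0.173 with an estimated correlation). Cholesterol synthesis genes had -0.06 (adjusted p = 0.0354, but adjusted p = 0.166 with an estimated correlation) and fetal or regenerative genes -0.12 (adjusted p = 0.042, but adjusted p = 0.173 with an estimated correlation). Adjusted over the list alone, 1 stem cell gene was higher, SMOC2 with 0.50, chosen after values were seen, and 0 members of the other 3 lists were called. These calls rested on single libraries. Of all the lists called for M303, only the goblet list kept its call without either uninduced M303 library or without replicate 2 of induced M303. Without replicate 1 of induced M303 the fetal or regenerative list also kept its call. The stem cell call was also lost without either induced SOX9 library (adjusted p = 0.055 and 0.0557).

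Inducing GFP, the control for doxycycline and for any induced protein, called 0 genes by edgeR. The counted genes do not include GFP, so its induction was not checked here. LYZ had a log2 fold change of 0.02, MUC2 -0.13, OLFM4 -0.02 and KRT20 -0.02, none called. An unadjusted p under 0.05 was seen for 580 genes, the smallest adjusted p was 0.169, and DESeq2 called 2. Without replicate 1 of uninduced GFP the edgeR count was 9. The only list called was the mitochondrially encoded genes, with a median of -0.26, 0 members called over all genes and 8 lower adjusted over the list alone (camera adjusted p = 2.87e-14, but adjusted p = 0.437 with an estimated correlation). Their share of counts was 1.52% ± 0.09 without and 1.27% ± 0.06 with doxycycline in the GFP line (SD, n = 2). It was 1.37% ± 0.08 and 1.33% ± 0.04 in the M303 line, and 1.47% ± 0.0035 and 1.31% ± 0.11 in the SOX9 line. Over the lines together the mean difference, with minus without doxycycline, was -0.145 percentage points. An exact permutation of doxycycline within each line, which was not among the planned tests, gave p = 0.0185.

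Set against GFP induction, the response to SOX9 was called for Paneth and goblet cell genes that included LYZ, DEFA6, PLA2G2A and MUC2, and not for DEFA5 or TFF3. The interaction asks which SOX9 responses exceed those of doxycycline and GFP. LYZ had a difference of 3.48 (SE 0.13, adjusted p = 1.12e-12), DEFA6 3.62, TCN1 3.76 and PLEKHS1 3.82. KLK3 had -1.99, FABP2 -1.91, ZG16 -1.74, KRT20 -1.58 and MUC2 -1.42. In all 163 genes were called, 115 higher and 48 lower, and DESeq2 called 227. The count was 108 without replicate 1 and 95 without replicate 2 of induced SOX9. The split was 126 higher and 103 lower without replicate 1 of uninduced GFP, and 82 and 29 without its replicate 2. DEFA5 had a difference of 5.02 that was not called (adjusted p = 0.188), with counts of 2 to 24 per library in the induced GFP line. CDX2, with -0.36 (adjusted p = 0.326), TFF3, with -1.01 (adjusted p = 0.134), and FABP1, with -1.50 (adjusted p = 0.0516), were not called in this test.

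By list, goblet genes were lower (median -0.83; 11 of 23 lower and 0 higher over all genes, 16 and 1 adjusted over the list alone) and Paneth genes higher (median 2.17; 3 of 6 and 0 lower over all genes, 4 and 0 adjusted over the list alone). Camera adjusted p was 1.32e-31 and 1.30e-33, and 2.99e-04 and 0.0012 with an estimated correlation. Stem cell genes (median 0.22; 3 of 16 higher and 0 lower, 7 and 1 adjusted over the list alone; adjusted p = 0.0047 with an estimated correlation) and WNT targets (median 0.18; 2 of 17 higher and 0 lower, 4 and 0 adjusted over the list alone; adjusted p = 0.0097 with an estimated correlation) were higher. Cholesterol synthesis genes were lower, with a median of -0.17, 1 of 22 higher and 1 lower over all genes, and 1 and 6 adjusted over the list alone (adjusted p = 0.0476 with an estimated correlation). Camera also called 4 lists that were lost with an estimated correlation. These were enterocyte genes (median -0.22; 1 higher and 3 lower, 3 and 7 adjusted over the list alone; adjusted p = 0.0507 with an estimated correlation) and tuft cell genes (0.67; 0 called by either count; adjusted p = 0.104 with an estimated correlation). The others were YAP targets (0.21; 1 higher, NT5E, and 3 higher and 1 lower adjusted over the list alone; adjusted p = 0.0917 with an estimated correlation) and mesenchymal genes (0.29; 1 higher, TGFBI, and 2 adjusted over the list alone; adjusted p = 0.104 with an estimated correlation). Without replicate 1 of uninduced SOX9 the enterocyte, tuft and YAP calls were lost (adjusted p = 0.0533). The enterocyte and tuft calls were also lost without replicate 1 of uninduced GFP (0.0521 and 0.0999) and of induced SOX9 (0.104), and the tuft call without replicate 2 of uninduced SOX9 (0.0536). Without replicate 2 of induced GFP the tuft and YAP calls were lost (0.160 and 0.118), and without replicate 2 of uninduced GFP the YAP call (0.0651). The single calls of NT5E (0.0530, replicate 1) and TGFBI (0.0620, replicate 2) were lost without 1 induced SOX9 library.

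Set against GFP induction, the response to M303 again had 1 called gene, SOX9, with a difference of 1.17 (SE 0.10, adjusted p = 7.92e-06). LYZ had -0.34, TFF3 -0.73 and KRT20 -0.50, none called. An unadjusted p under 0.05 was seen for 717 genes and DESeq2 called 1. Without replicate 1 of uninduced GFP the count was 12. Goblet genes had a median of -0.20 and a mean of -0.02 (camera adjusted p = 0.0055, but adjusted p = 0.227 with an estimated correlation). Mitochondrially encoded genes had a median of 0.20 (camera adjusted p = 0.0014, but adjusted p = 0.524 with an estimated correlation). Over all genes 0 members of either list were called; adjusted over the list alone, 0 goblet genes were called and 1 mitochondrially encoded gene was lower. Neither list was called without replicate 1 of induced M303 (adjusted p = 0.159 and 0.119). The goblet call was also lost without replicate 2 of uninduced GFP (0.0514) or replicate 1 of uninduced M303 (0.0894). The mitochondrial call was lost without replicate 1 of uninduced GFP (0.482), replicate 2 of induced GFP (0.0588) or replicate 2 of uninduced M303 (0.129).

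Wild-type SOX9 and M303 differed in several genes of Paneth and goblet cells, though not in DEFA5 by this test. LYZ rose more with SOX9 by 3.82 on the log2 scale (SE 0.13, adjusted p = 1.94e-13), TCN1 by 4.63, PLEKHS1 by 3.16, DEFA6 by 2.98, PLEKHB1 by 2.50 and IFI6 by 2.28. The lowest differences under the naming rule were -1.95 for B3GALT5, -1.77 for KLK3, -1.71 for FABP2 and -1.42 for MUC2 (adjusted p = 8.16e-04). GUCY2C, the guanylin receptor, had -1.07. This interaction asks whether the shortened form acts as the full one does. It called 89 genes, 65 higher and 24 lower with SOX9, and DESeq2 called 139, among them all 89. Without replicate 2 of induced SOX9 the count was 57, and without replicate 1 of uninduced M303 the lower genes numbered 13. DEFA5 had a difference of 4.26 that was not called (SE 0.82, adjusted p = 0.0711). DEFA6 was lost without replicate 2 of uninduced M303 (adjusted p = 0.0608) and B3GALT5 without 7 of the libraries, up to adjusted p = 0.257 without replicate 2 of uninduced SOX9. KLK3 was lost without 5, up to 0.164 without replicate 1 of uninduced M303, and FABP2 without 4, up to 0.148 without replicate 1 of induced SOX9.

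The difference between both forms was seen in 4 lists under either correlation. Goblet genes had a median difference of -0.56, with 6 of 23 lower and 0 higher over all genes and 13 lower and 1 higher adjusted over the list alone (camera adjusted p = 1.76e-22, and 7.76e-04 with an estimated correlation). Paneth genes had 1.91, with 3 of 6 higher and 0 lower over all genes and 4 and 0 adjusted over the list alone (camera adjusted p = 2.29e-41, and 7.76e-04 with an estimated correlation). Stem cell genes had 0.25, with 2 of 16 higher, OLFM4 and SMOC2, and 7 adjusted over the list alone (camera adjusted p = 2.48e-07, and 0.0091 with an estimated correlation). WNT targets had 0.23, with 2 of 17 higher, APCDD1 and NKD1, and 3 adjusted over the list alone (camera adjusted p = 4.28e-05, and 0.0168 with an estimated correlation). The call of OLFM4 was lost without replicate 1 of induced SOX9 (adjusted p = 0.0601). OLFM4 started at 59.1 CPM in the uninduced M303 line and 42.3 CPM in the uninduced SOX9 line. With doxycycline it stood at 60.8 and 70.1 CPM. KRT20 and CDX2, with differences of -1.08 and -0.41, were not called (adjusted p = 0.159 and 0.301).

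Camera called 6 more lists for this difference, and their calls were lost with an estimated correlation. The enterocyte list had 1 higher (MUC13) and 2 lower (LGALS4 and FABP2) over all genes, 3 and 6 adjusted over the list alone (adjusted p = 0.0922 with an estimated correlation). In the YAP list 1 was higher, IGFBP3, and 2 adjusted over the list alone (adjusted p = 0.0922 with an estimated correlation). In the mesenchymal list 0 were called over all genes and 3 were higher adjusted over the list alone (adjusted p = 0.0922 with an estimated correlation). In the cholesterol synthesis list 1 was higher, HMGCS1, and 1 higher and 1 lower adjusted over the list alone (adjusted p = 0.0983 with an estimated correlation). No member was called over all genes in the enteroendocrine list (adjusted p = 0.133 with an estimated correlation) or the mitochondrially encoded list (adjusted p = 0.475 with an estimated correlation); adjusted over the list alone 1 enteroendocrine gene was lower. Of the 10 lists called by camera for this difference, 5 were called without replicate 1 of uninduced SOX9, and 6 without replicate 2 of uninduced M303 or replicate 1 of induced M303. LGALS4 was lost without any 1 of 3 libraries (highest adjusted p = 0.0655, without replicate 1 of induced SOX9) and IGFBP3 without any 1 of 8 (highest adjusted p = 0.337, without replicate 2 of induced SOX9).

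Across genes, the log2 fold changes of SOX9 and M303 induction, which share no libraries, had a Pearson correlation of 0.06 and a Spearman correlation of 0.12 over all 18219 genes. Over the 12024 genes with a mean of at least 1 log2 CPM, without SOX9, these were 0.25 and 0.23. For SOX9 and GFP induction the same values were 0.06 and 0.06 over the 12024 genes. Genes are not independent replicates, so no p is given. Of the genes called for SOX9 induction only SOX9 was also called for M303 induction. Leaving out replicate 2 of induced M303 turned the correlation over all genes to -0.02.

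**Figure D4:**
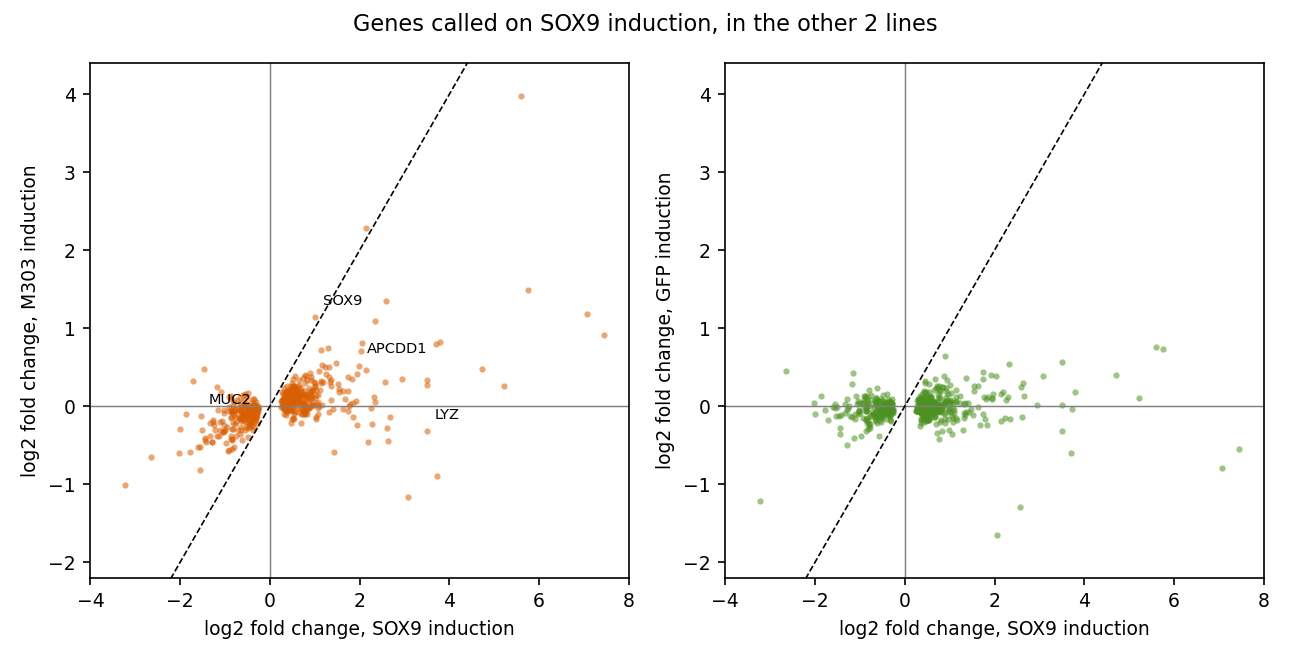
Log2 fold change on M303 induction (left, vertical axis) and on GFP induction (right, vertical axis) against that on SOX9 induction (horizontal axes) for genes called on SOX9 induction; each dot is a gene and the dashed line marks equal change. LYZ lies at 3.50 for SOX9 and -0.32 for M303, and SOX9 lies at 1.00 and 1.14.

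Before induction the lines differed in 1 called gene. OLFM4 was higher in the uninduced M303 line, at 59.1 ± 0.66 CPM, than in the uninduced GFP line, at 37.5 ± 0.96 CPM (SD, n = 2; log2 difference 0.66, SE 0.09, adjusted p = 0.0041). This call was lost without replicate 2 of uninduced GFP (adjusted p = 0.173), replicate 1 (0.117) or replicate 2 (0.0632) of uninduced M303. SOX9 itself differed from the GFP line by -0.05 in the M303 line and -0.10 in the SOX9 line, neither called. The comparisons ask whether the lines differ without doxycycline, leaky expression included. For the M303 line 1110 genes had an unadjusted p under 0.05 and DESeq2 called 1. For the SOX9 line edgeR called 0 genes, 866 had an unadjusted p under 0.05, and DESeq2 called 2. Without replicate 1 of uninduced GFP the counts were 56 for the M303 line and 39 for the SOX9 line, and without either induced GFP library the latter was 1.

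Among the lists, 0 were called for the uninduced SOX9 line; the smallest camera adjusted p was 0.104, for the interferon and NF-kB lists. For the uninduced M303 line, Paneth genes had a median of 0.31 (camera adjusted p = 0.0416, but adjusted p = 0.442 with an estimated correlation). Mitochondrially encoded genes had -0.11 (camera adjusted p = 0.0049, but adjusted p = 0.550 with an estimated correlation). In both lists 0 members were called over all genes and 0 adjusted over the list alone. Both calls were lost without replicate 1 of uninduced GFP (adjusted p = 0.148 and 0.881) or replicate 2 of uninduced M303 (adjusted p = 0.390 and 0.211), and the Paneth call also without replicate 2 of induced SOX9 (0.0522).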

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

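All tests that weigh an explanation here were chosen after the results were seen; the differences between inductions were planned. Of the former, the split of the doxycycline test by direction and its added bound, the reference set of the RNA mixing test, the bound of the construct RNA test and the deciding test for the uninduced GFP library were also revised after a first outcome had been seen. Results are listed where the same contrast differed between lines by an interaction test.

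The response to SOX9 differed from that to GFP in 163 genes, the response to M303 from that to GFP in 1 (SOX9), and the response to SOX9 from that to M303 in 89. Among the named genes called for this difference, log2 differences of SOX9 minus M303 induction were highest for TCN1 (4.63), LYZ (3.82), PLEKHS1 (3.16), DEFA6 (2.98), PLEKHB1 (2.50) and IFI6 (2.28). The value of TCN1 is imprecise (SE 0.62), with counts of 8 to 30 per library in the induced M303 line. In the uninduced SOX9 line TCN1 and PLEKHS1 stood at 0.71 and 1.02 CPM. COL9A3 (1.80), APCDD1 (1.46), HMGCS1 (1.17), PLA2G2A (0.85), NKD1 (0.84), SMOC2 (0.81), OLFM4 (0.69), MUC13 (0.67), CD24 (0.63) and IGFBP3 (0.63) also rose more with SOX9. LGALS4 (-0.53), REG4 (-0.71), IL33 (-0.78), ATOH1 (-1.01), GUCY2C (-1.07), MUC2 (-1.42), FABP2 (-1.71), KLK3 (-1.77) and B3GALT5 (-1.95) were lower. Of these genes 8 lost the call without some library: COL9A3, KLK3, OLFM4, FABP2, IGFBP3, DEFA6, LGALS4 and B3GALT5, with COL9A3 at adjusted p = 0.202 without replicate 1 of uninduced M303. Median differences of lists were 1.91 (Paneth cell), -0.56 (goblet cell), 0.25 (intestinal stem cell) and 0.23 (WNT target). They were 0.29 (mesenchymal and TGF-beta), 0.11 (YAP target), -0.17 (enterocyte differentiation), -0.17 (cholesterol synthesis), -0.16 (mitochondrially encoded) and -1.21 (enteroendocrine cell), and these 6 list calls were lost with an estimated correlation. The enteroendocrine median rests on 7 tested genes. Only 1 gene of that list had a mean of at least 1 CPM in the uninduced libraries.

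Genes called on SOX9 induction shifted slightly the same way with M303: of 329 raised genes 259 (78.7%) had a positive M303 fold change (median 0.09, p = 0.0029 with an estimated correlation), and of 211 lowered genes 179 (84.8%) a negative one (median -0.10, p = 0.0053 with an estimated correlation). For the raised genes the slope on the SOX9 fold changes was 0.152 for M303 (0.0841 to 0.201 without 1 M303 or GFP library). For GFP it was 0.00306 (-0.0683 to 0.0388), and M303 against GFP gave camera p = 0.0137 with an estimated correlation. The counted genes do not include GFP, so whether GFP was made is not known. Doxycycline, or any induced protein if GFP was made, is argued against as the whole cause for these raised genes. For the lowered genes it stays open: the slopes were 0.212 (0.199 to 0.243) and 0.0693 (0.0164 to 0.106), but M303 against GFP, with 69.2% of them lower (camera p = 3.87e-05), gave p = 0.106 with an estimated correlation, and 142 genes (67.3%) were also lower with GFP (camera p = 0.0012, and 0.184 with an estimated correlation). RNA of SOX9-induced cells in the M303 libraries is argued against as the sole source, since genes raised at least 4-fold would need 1.505% of it (95% bootstrap interval -1.80 to 4.67, 12 genes) and the called genes 15.6% (13.6 to 18.3, 517 genes); at that share LYZ would rise by 1.38, and it had -0.32. A weak activity of M303 on part of these genes may explain the shift, and this stays a hypothesis.

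M303 induction called 1 gene where SOX9 induction called 541. The SOX9 counts argue against less SOX9 RNA in total with M303. Their rises differed by -0.14 (SOX9 minus M303), with an upper 95% bound of 0.07 against a rise of 1.00. These counts pool endogenous and construct transcripts in unknown shares, so they cannot decide whether the M303 line held less construct RNA. Lower power as the whole reason is argued against by the slope of 0.163, at most 0.205 without any 1 M303 or GFP library. Equal effects would give a slope near 1, or somewhat below it because the genes were chosen by their SOX9 response. SOX9 libraries were not left out for this slope. Less construct RNA, less M303 protein, or a lost function of the shortened form may explain the difference. The design names the last, and none was tested. Each construct was in its own line, so a response particular to the line cannot be told apart from these.

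When replicate 1 of uninduced GFP was left out, 56 genes were called for the uninduced M303 line and 39 for the uninduced SOX9 line, against 1 and 0 with it; all 56 were lower in replicate 2 than in replicate 1 (median -0.64), and 10 were ribosomal protein genes. The lower level in replicate 2 follows from picking these genes against that library alone, so it is no separate evidence. Of the 18219 genes tested, 78 were ribosomal protein genes. Counts of ribosomal protein genes made up 6.06% and 5.18% of the uninduced and 5.45% and 6.32% of the induced GFP libraries, and 6.04% to 6.45% elsewhere. If a shared library effect on such transcripts were the source, the 56 genes would also be lower in induced GFP replicate 1 than 2, and 44 were (median -0.21), which lies between the bounds set for the test. The 2 libraries with the lowest shares also stood apart on the second principal component (48.0 and 31.7, against -27.5 to 10.9 elsewhere), as a shared effect would have it, but that component covers all genes, so this and a real difference of that sample cannot be told apart. With the ribosomal share as covariate 0 of the 56 were called by edgeR, but that covariate may absorb the lone library.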

How the results depend on the processing

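The covariate for the ribosomal protein gene share was chosen after the results were seen; the other alternatives here were planned. Over all alternatives together, among the single named genes 3999 values kept their side of the threshold, 145 were weaker, 17 stronger and 0 reversed. The 3999 include 83 values that changed sign, of genes called neither as reported nor in the alternative. Among the list calls 631 held, 89 were weaker and 0 reversed. Of 57 named genes called for SOX9 induction, 39 were called in every setting and 18 were lost without some library. DESeq2 was not run for the lists.

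Without a low-count filter the counts were 9 (M303), 4 (GFP), 270 (SOX9 against GFP), 11 (M303 against GFP), 147 (SOX9 against M303), 17 (uninduced SOX9) and 22 (uninduced M303), where more low-count genes enter the test. With only the libraries of the contrast they were 3 (M303) and 1 (uninduced SOX9). DESeq2 called 3 (M303), 2 (GFP), 139 (SOX9 against M303) and 2 (uninduced SOX9). An absolute log2 fold change of at least 1, which by construction keeps fewer, left 118 (SOX9), 72 (SOX9 against GFP), 42 (SOX9 against M303) and 0 (uninduced M303, where 1110 genes had an unadjusted p under 0.05 in edgeR and DESeq2 called 1). With the ribosomal share as covariate the uninduced M303 count was 0 and the SOX9 induction count 695.

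Leaving out 1 library gave 231 to 675 calls (SOX9), 1 to 2 (M303), 0 to 9 (GFP), 95 to 229 (SOX9 against GFP), 1 to 12 (M303 against GFP), 57 to 107 (SOX9 against M303), 0 to 39 (uninduced SOX9) and 0 to 56 (uninduced M303). The lone library was then assumed to vary like the other groups. Lists called ranged from 9 to 11 (SOX9), 1 to 6 (M303), 6 to 11 (SOX9 against GFP), 0 to 2 (M303 against GFP), 5 to 10 (SOX9 against M303) and 0 to 4 (uninduced M303). With an estimated correlation the lists were 8 (SOX9), 1 (M303), 0 (GFP), 5 (SOX9 against GFP), 0 (M303 against GFP), 4 (SOX9 against M303) and 0 (uninduced M303). Without a filter they were 2 (M303) and 1 (uninduced M303), and with only the libraries of the contrast 8 (M303).

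The correlation of SOX9 and M303 effects, 0.055 over all genes, was 0.0163 without a filter, 0.235 for genes with at least 1 CPM in 2 libraries and 0.0911 with only the libraries of the contrast. Without 1 library it ran from -0.019, where it reversed, to 0.0723. Low-count genes dilute it, as the first pair of values shows; for the other changes the cause was not tested. Replicate numbers did not pair the samples, with correlations of deviations from -0.079 to 0.052 over 15 pairs of groups. The replicate block gave 452 calls (SOX9, 451 of them shared), 1 (M303), 0 (GFP), 139 (SOX9 against GFP) and 78 (SOX9 against M303). At this depth, replicate number and spread together, which were not varied apart, 68.7% of 67 simulated 1.5-fold changes were called for M303 induction. These were drawn among genes with a mean of at least 2 CPM, out of 17545 tested. All planted changes were present together and gave 194 calls, against 1 call in the data. With more calls the adjusted threshold is easier to pass. The share therefore overstates the power for M303 induction if few genes changed.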

Other observations

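Apart from GUCY2C, KLK3 and SMOC2, which the naming rule selects, the genes in this part were chosen after the results were seen. Their tests were planned.

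Genes outside the lists also changed on SOX9 induction. The secreted protease PRSS23 rose by 1.51 on the log2 scale, from 104 to 296 CPM (n = 2, edgeR adjusted p = 7.20e-11), and the amino acid transporter SLC6A14 by 1.77, from 19.5 to 66.3 CPM (adjusted p = 9.93e-09). SMOC1, the relative of the stem cell gene SMOC2, rose by 1.63 (adjusted p = 1.30e-07), and the kallikrein KLK6 by 1.00 (adjusted p = 2.31e-07), while KLK3 fell. The surface proteins CD109 and TM4SF1 rose by 1.24 and 1.02, the proteoglycan VCAN by 1.23 and the antioxidant enzyme SOD3 by 0.98. The adaptor NEDD9 rose by 1.79, the transcription factor RUNX1 by 1.15 and the receptor NTRK2 by 2.24. CD74, the invariant chain of antigen presentation, rose by 1.82 (adjusted p = 9.08e-07).

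GUCY2C, GREM1 and SLC6A20, also outside the lists, fell. GUCY2C, the receptor of the gut hormone guanylin, had a log2 fold change of -1.27, from 32.2 to 13.3 CPM (edgeR adjusted p = 2.15e-07). The BMP antagonist GREM1 had -0.82, from 173 to 98.1 CPM (adjusted p = 3.70e-07), and the proline transporter SLC6A20 -0.84 (adjusted p = 4.49e-07). With M303 the log2 fold changes were -0.20, -0.06 and -0.04 for these 3 genes. The differences from SOX9 induction were called for all 3 (adjusted p = 5.96e-04 for GUCY2C and 3.42e-04 for both GREM1 and SLC6A20). Of the raised genes, VCAN was not called as different from M303 (adjusted p = 0.0695).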
